A study of Mus musculus with 8 samples.

How the data were processed

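Gene expression was measured on 8 Affymetrix arrays in the organ of Corti, the sensory strip of the cochlea, of mice at postnatal day 16. Per the labels' protocols, total RNA was isolated with the mirVana kit, and 75 to 125 ng of it was amplified and labelled with biotin in 2 cycles. The deposited values are an intensity per probe set on a linear scale, MAS5 signals scaled by the authors so that the trimmed mean of each array (2% off each end) is 500. The submitters' processing notes name MAS5 and the affy package, version 1.26, without the role or order of each. The array version, the scanner settings and detection calls are not given in the sources used here. No array was brought to the distribution of another before deposit, since the medians differ between arrays.

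Each of the 4 groups (control apex, control base, Dicer1 conditional knockout apex, Dicer1 conditional knockout base) holds 2 samples. Groups and replicate numbers were read from the sample titles. The labels tie a replicate to the segments of 1 mouse, so the apical and the basal sample of 1 genotype and number were treated as coming from the same mouse, giving 4 presumed mice. This was checked in the data: Xist and the Y-linked genes were alike in the apex and base of each control mouse. Deviations from the group mean correlated across genes between apex and base of the same number in controls (r = 0.339). In knockouts that correlation was weak (r = 0.0683) and gave little evidence of the pairing. Of the genes that differed over 2-fold between the replicates of a genotype in both regions, 104 of 122 did so in the same direction in controls and 16 of 18 in knockouts. Across genotypes the replicate number is only shared.

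The table held 45101 probe sets, 64 of them array controls. Probe sets were assigned to genes by the supplied annotation: 34945 had 1 gene, 932 had several and 9160 had none listed, and 34741 of the first were matched by Entrez identifier. Genes were read from the probe set of highest mean log2 value among those with 1 gene, which gave 18193 genes. Probe sets under the 40th percentile of mean log2 value (5.274, a signal of 38.71) were not tested, leaving 13221 genes. Values were log2 transformed with no pseudocount and no further normalization between arrays. Genes named in the fixed lists that have no probe set under these rules were not analysed here.

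limma 3.58.1 on R 4.3.3 was fitted to the 4 group means of all 8 samples, with empirical Bayes moderation and an intensity trend (4 residual degrees of freedom, 3.46 from the prior). Contrasts were knockout minus control in each region, base minus apex in each genotype, their mean, and the difference of the genotype effects between regions. The genotype effect over both regions was fitted on the mean of the apical and basal value of each presumed mouse (2 residual degrees of freedom, 3.1 from the prior), so that no mouse counted more than once. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05; at an unadjusted p under 0.05, 661 genes are expected by chance. Standard errors come from the moderated fit.

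For the text, the rule named in each contrast the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. Where fewer passed, genes of smallest p made up the number to 5 in each direction and are given as not past the threshold. Up to 4 members of smallest p were named from each described list, and Dicer1 and a fixed set of hair cell, glial, neuronal and sex markers were always named. Lists of cell type markers and pathways, 26 with 348 genes, were fixed with the groups, the contrasts, the naming rule and the alternative settings before the data were examined; 25 lists had the 3 tested members required. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. List tests were adjusted over the lists of a contrast. A pair of further lists, neutrophil granule and erythroid precursor, was chosen after the data were seen.

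Alternatives covered the filter (none, or the 60th percentile), a pseudocount of 16, quantile normalization, centring on the 75th percentile, the mean of a gene's probe sets or every probe set, the variance model, the presumed mouse as a fixed or random block, the compared groups alone, another threshold, low values raised to the filter, and leaving out each sample. Chromosome names came from RefSeq genes on GRCm38.p6. The procedure was tested on simulated data with 13221 genes and groups of the real size: of 100 genes shifted by a log2 change of 2, it recovered 69.8% for the genotype in the apex, 68.2% in the base, 24.2% for the difference between regions and 86.6% for base against apex over both genotypes. At a log2 change of 1 these shares were 18%, 16.8%, 0.4% and 42.8%. The simulated noise was independent between samples and alike in all groups, with no mouse effect and no sample that stood apart. In the real data 290 genes had an unadjusted p under 0.05 for the genotype in the apex and 149 for the difference between regions, where 661 are expected. The shares recovered in the real data may therefore be lower. The number of arrays limits the precision of every value.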

Results

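The organ of Corti of mice at postnatal day 16 was divided into an apical and a basal part, and gene expression was measured on 1 array per part. Mice carried Atoh1-Cre, which drives recombination in hair cells, and either 2 floxed Dicer1 alleles (conditional knockout, cKO) or 1 (littermate control). Dicer1 encodes the enzyme that makes mature microRNAs. Each of the 4 groups held 2 samples, so that 4 presumed mice gave 8 arrays. Median signals ran from 67.3 to 100 per array at a trimmed mean of 500. Across genes, the log2 values of replicates correlated at r = 0.9615 to 0.9779 in 3 groups and at 0.9279 in control base, and the 20 pairs of samples that shared neither group nor presumed mouse at 0.9254 to 0.9774. Control base replicate 1 correlated more closely with each of the other 6 samples, from 0.9529 for cKO base replicate 2 to 0.968 for control apex replicate 1, than with its replicate. The number of arrays limits the precision of every value below.

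Transcripts of tissues beside the sensory epithelium varied between samples of the same group. Dct, a melanin enzyme made by pigment cells of the stria vascularis, had a log2 signal of 13.88 in control base replicate 2, 13.91 and 13.65 in the cKO basal samples, and 5.96 in control base replicate 1. In the apical samples it was 11.87 in control replicate 1, 6.19 in control replicate 2, and 6.91 and 9.36 in the cKO. Tectb, a tectorial membrane gene of the apical turn, was at 5.71 in control base replicate 1 and 12.52 in control apex replicate 1, so both samples held the region their labels state. Xist, transcribed from the inactive X chromosome, was at 12.54 and 12.39 in the apex and base of control mouse 1 and at most 8.23 elsewhere, so control mouse 1 was female and the other 3 mice male.

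**Figure D1:**
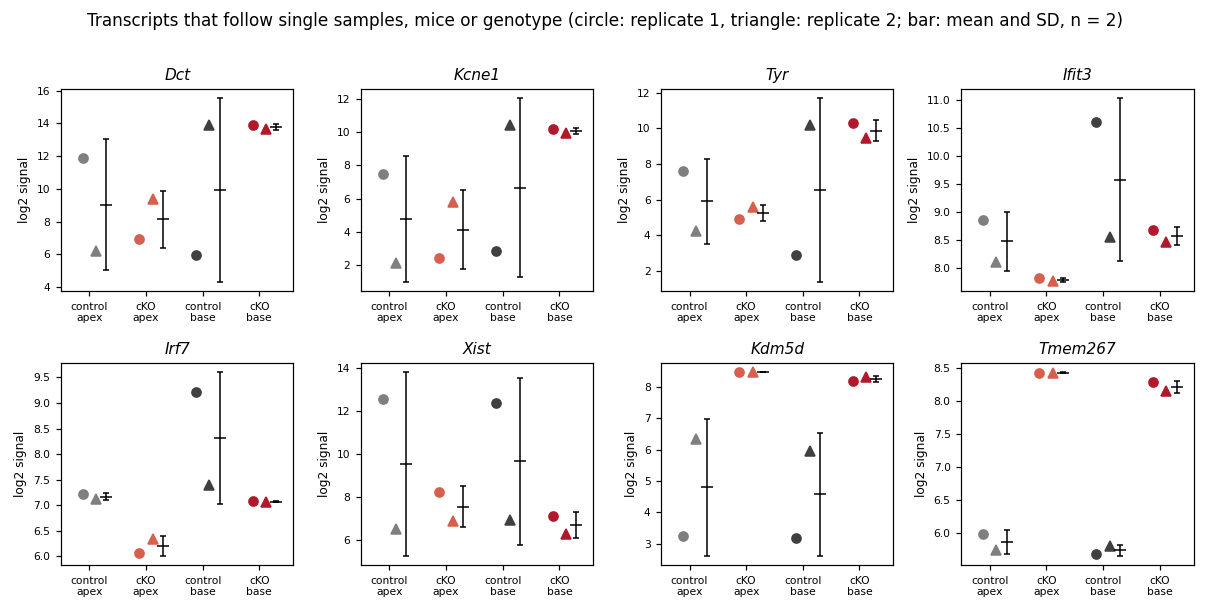
Log2 signal of 8 transcripts in each sample (circle, replicate 1; triangle, replicate 2; bar, mean and SD, n = 2). Dct was at 5.96 in control base replicate 1 against 13.65 to 13.91 in the other basal samples, and Xist was high in both samples of control mouse 1.

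Dicer1 transcript levels were close in all 4 groups: a mean log2 signal of 9.38 ± 0.27 (SD, n = 2) in control apex, 9.29 ± 0.17 in cKO apex, 9.20 ± 0.23 in control base and 9.18 ± 0.17 in cKO base. cKO minus control was -0.09 ± 0.22 (log2, SE) in the apex and -0.02 ± 0.22 in the base (adjusted p = 1 in both, limma). The position of its probes relative to the floxed part of the gene is not known, so these values do not measure recombination. The second Dicer1 probe set gave -0.21 and -0.29. Atoh1, the hair cell fate factor, and Slc26a5, the outer hair cell motor prestin, lay under the filter. Slc26a5 had mean log2 signals of 5.17 ± 0.19 in control apex, 5.10 ± 0.07 in cKO apex, 3.15 ± 1.54 in control base and 1.57 ± 0.23 in cKO base, and Atoh1 of 5.40 ± 0.45, 4.69 ± 1.03, 4.71 ± 1.20 and 4.37 ± 0.31.

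**Figure D2:**
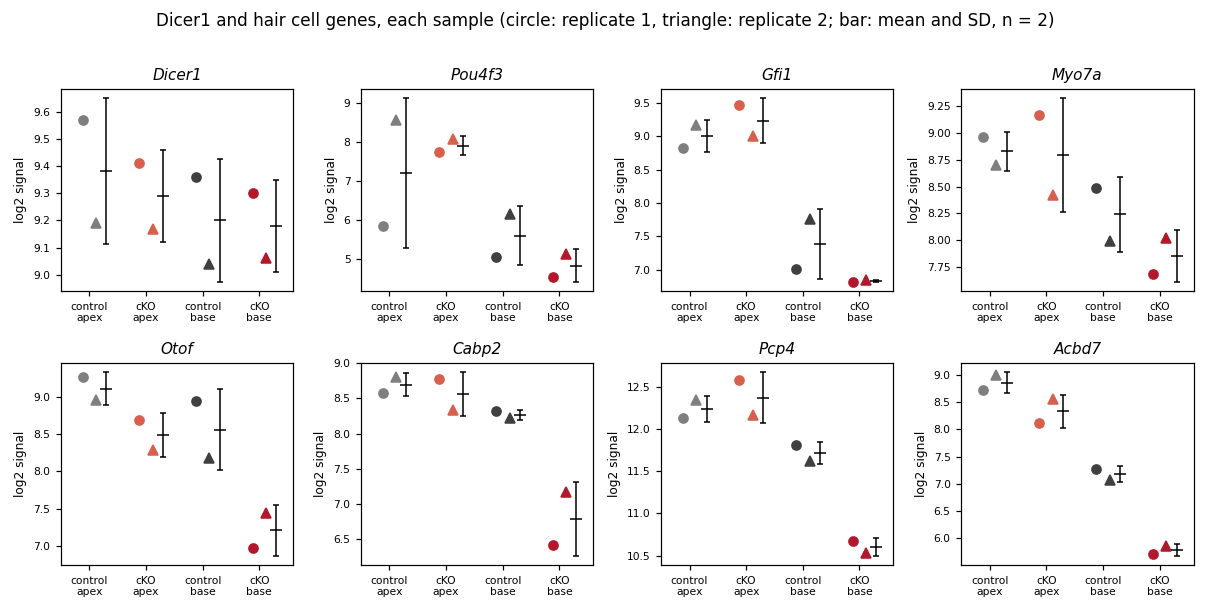
Log2 signal of Dicer1 and 7 genes expressed in hair cells in each sample (circle, replicate 1; triangle, replicate 2; bar, mean and SD, n = 2). Gfi1, Otof, Cabp2, Pcp4 and Acbd7 were lower in both cKO basal samples than in every other sample, although none passed the test between genotypes.

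The first question was what loss of Dicer1 in hair cells did to the apex, where 2 cKO samples were compared with 2 controls. Of the hair cell markers set to be named in every comparison, Myo7a, a stereocilia myosin, gave -0.03 ± 0.31 (log2, SE), Gfi1, a hair cell transcription factor, 0.23 ± 0.31, and Pou4f3, which hair cells need to survive, 0.70 ± 0.82. Other hair cell genes gave larger differences that did not pass, such as the calcium channel Cacna1d (0.56 ± 0.22), Otof, which couples calcium to vesicle release (-0.61 ± 0.32), and the calcium buffer Calb1 (0.93 ± 0.57). Sox2, a supporting cell factor, gave -0.04 ± 0.23, the myelin gene Mbp 0.24 ± 0.11 and the neuronal tubulin Tubb3 -0.43 ± 0.57. The smallest p belonged to Tmem267, a little-studied transmembrane protein, 5.92-fold higher in the cKO (2.57 ± 0.25, adjusted p = 0.134). Pnmt, the enzyme that makes adrenaline, gave 1.55 ± 0.29. Crybb3, a lens crystallin, the olfactory receptor gene Olfr701 and Fbxl8 had control means under the filter's signal and were at least 1.76-fold, 2.34-fold and 1.66-fold higher, with low samples taken at that signal. On the lower side stood Clasrp (-1.66 ± 0.24), Rpgrip1, a ciliary scaffold (-1.41 ± 0.23), Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus (-1.53 ± 0.30), the metalloreductase Steap4 (-1.02 ± 0.20) and Trmt2b (-0.89 ± 0.18). No gene passed limma's adjusted threshold (0 of 13221), and 290 had an unadjusted p under 0.05, 146 higher and 144 lower in the cKO, where 661 are expected by chance.

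Among the fixed lists, camera at the preset correlation called 4 of 25 in the apex. Tectorial and spiral limbus matrix was higher (median 0.31, 9 of 11 members, Col9a1 at 0.39 ± 0.13 and Col2a1 at 0.47 ± 0.20, both cartilage-type collagens) with adjusted p = 0.0293. Fibrocyte and mesenchyme was higher too (median 0.22, 12 of 13 members, the secreted protein Otor at 0.30 ± 0.13) with adjusted p = 0.0293. Interferon response was lower (median -0.63, 6 of 6 members, Irf7, a master regulator of the response, at -0.96 ± 0.53) with adjusted p = 0.0293. Immediate early and heat shock was also lower (median -0.24, 9 of 11 members, the chaperone Hspa1a at -0.58 ± 0.27) with adjusted p = 0.0357. None of the 4 held with an estimated correlation (adjusted p = 0.819 for each with an estimated correlation), and no member passed limma over all genes. Adjusted over the list alone, Serpina3n of the glial scar and injury list was higher (0.92 ± 0.22), as was Celsr2 of the reported microRNA targets (0.74 ± 0.17). Every one of the 4 calls was lost without control apex replicate 1, from the female mouse, with medians of 0.05, 0.14, -0.29 and -0.22 in the order given. Each was also lost without a cKO sample: tectorial (0.29) and interferon (-0.56) without cKO apex replicate 2, fibrocyte (0.12) without cKO apex replicate 1, and immediate early without either (-0.18 and -0.31). The hair cell lists were not called: hair bundle and mechanotransduction had a median of 0.13 (adjusted p = 0.16), hair cell transcription factors and soma 0.15, outer hair cell 0.10, and inner hair cell and ribbon synapse -0.12. Supporting cell (-0.01, mean 0.06), stria vascularis (-0.55) and cell cycle genes (0.14) were not called either.

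In the base, no gene passed the test between genotypes, and members of the hair cell lists went both ways. Cabp2, a calcium sensor of the inner hair cell synapse, was 2.81-fold lower (-1.49 ± 0.30, log2, SE), and Otof gave -1.35 ± 0.32, while Calb1 gave 1.37 ± 0.57. The calmodulin regulator Pcp4 gave -1.11 ± 0.18 and the acyl-CoA-binding gene Acbd7 -1.39 ± 0.25. Lgals3bp, a secreted scavenger receptor protein, gave -1.02 ± 0.20 and the interferon-induced Oasl2 -1.57 ± 0.32. Higher were Tmem267 (2.48 ± 0.25, adjusted p = 0.168, the smallest), Pnmt (2.83-fold), the erythroid factor Gata1 (at least 2.98-fold, with control samples under the filter's signal taken at it), and the neutrophil granule genes Prtn3 (1.62 ± 0.36) and Camp (1.28 ± 0.29). Gfi1 gave -0.55 ± 0.31, Pou4f3 -0.76 ± 0.82 (its cKO mean under the filter's signal), Myo7a -0.39 ± 0.31, Sox2 -0.27 ± 0.23, Mbp 0.07 ± 0.11 and Tubb3 -0.45 ± 0.57. Again 0 genes passed limma's adjusted threshold, and 413 had an unadjusted p under 0.05, 217 higher and 196 lower. Without control base replicate 2 the only basal control was replicate 1, from the female and low in stria vascularis transcripts. A count of genes from that fit cannot be read as an effect of genotype.

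Camera called 13 of 25 lists in the base, 8 higher and 5 lower, and none with an estimated correlation (smallest adjusted p = 0.424 with an estimated correlation). Of the hair cell lists, inner hair cell and ribbon synapse was lower (median -0.28, 8 of 10 members, adjusted p = 0.00175), with 3 members past the threshold adjusted over the list alone (Cabp2, Otof and the cochaperone Dnajc5b, at -1.02 ± 0.30) and 0 over all genes. Hair cell transcription factors and soma was lower too (median -0.43, 10 of 16 members, adjusted p = 0.00757), with Cabp2, Otof and the cytoskeletal protein Smpx (-1.01 ± 0.24) past the threshold adjusted over the list alone. Hair bundle and mechanotransduction was lower (median -0.10, mean -0.23, 14 of 23 members, adjusted p = 0.0298), with the actin bundler Fscn2 at least 1.85-fold, stereocilin (Strc) at least 2.44-fold and the transduction channel Tmc1 at least 1.33-fold lower, since their cKO means lay under the filter's signal. With all such low values raised to the filter, the 4 calls of hair cell and supporting cell lists were kept, at a soma median of -0.15 and a hair bundle median of -0.10. Supporting cell genes were lower alongside them (median -0.25, 18 of 23 members, adjusted p = 0.0172), with the Notch ligand Jag1 at -0.60 ± 0.19, while outer hair cell was not called (median -0.32, 5 of 6 members, adjusted p = 0.0615). Stria vascularis genes were higher in the same samples (median 1.31). With an estimated correlation the adjusted p was 0.424 for each of these 4 calls. The hair bundle call was lost without any of the 4 basal samples (medians -0.10 and -0.17 without cKO replicates 1 and 2, -0.19 and -0.16 without control replicates 1 and 2). The soma call was lost without cKO base replicate 1 (-0.08), control base replicate 1 (-0.48) or control base replicate 2 (-0.25). The inner hair cell call was lost without control base replicate 1 (-0.26), and the supporting cell call without cKO base replicate 1 (-0.10) or control base replicate 2 (-0.08).

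Of the other lists called in the base, stria vascularis was higher (median 1.31, 11 of 11 members, the potassium channel Kcnq1 at 1.77 ± 1.08, adjusted p = 0.00116). Interferon response was lower (median -1.05, 5 of 6 members, the regulator Usp18 at -1.32 ± 0.45, adjusted p = 0.0019). Cell cycle was higher (median 0.45, 12 of 13 members, adjusted p = 0.00436), with the proliferation marker Mki67 at 1.36 ± 0.31 past the threshold adjusted over the list alone. Fibrocyte and mesenchyme (median 0.25, adjusted p = 0.00683), bone (0.22, mean 0.78, adjusted p = 0.00757, the gelatinase Mmp9 at 2.15 ± 0.83), tectorial and spiral limbus matrix (0.28, adjusted p = 0.0141), immediate early and heat shock (0.27, adjusted p = 0.0141, the stress factor Atf3 at 1.55 ± 0.56 and Fos at 1.53 ± 0.61), glial scar and injury (0.31, adjusted p = 0.0405) and p53 and apoptosis (0.12, adjusted p = 0.0421, the pro-death Bcl2l11 at 0.71 ± 0.24) were higher. The adjusted p with an estimated correlation ran from 0.424 to 0.535 over these 9 lists. All 9 calls were lost without control base replicate 1, from the female mouse and low in stria vascularis transcripts. The medians without it were -0.18 for stria vascularis, -0.14 for interferon response, 0.12 for cell cycle, 0.08 for fibrocyte, 0.06 for bone, 0.12 for tectorial, 0.27 for immediate early, -0.04 for glial scar and 0.10 for p53. Leaving out cKO base replicate 1 ended the calls of fibrocyte (0.08), bone (0.24), immediate early (0.01) and p53 (0.22). Leaving out cKO base replicate 2 ended those of cell cycle (0.22), tectorial (0.26), glial scar (0.13) and p53 (0.11), and leaving out control base replicate 2 those of immediate early (0.41) and p53 (0.23). The lists of microRNA machinery (median 0.15), reported microRNA targets (0.09), tonotopy candidates (0.05), Notch pathway (0.00, mean -0.04), neuron (0.00, mean 0.04), myelin and Schwann cell (0.03, mean -0.17), macrophage and leukocyte (0.12), red blood cell (0.31), skeletal muscle (0.57), endothelium (-0.05) and sex-linked genes (2.83) were not called in the base.

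Over apex and base together, with 1 mean per presumed mouse and 2 mice per genotype, the genes of smallest p were those shifted in both regions. Tmem267 was 5.75-fold higher in the cKO (2.52 ± 0.21, log2, SE, adjusted p = 0.74), followed by Pnmt (1.53 ± 0.25), Prtn3 (1.29 ± 0.23), G530011O06Rik (at least 2.11-fold, its control means under the filter's signal) and the calcium-dependent kinase Camkk2 (0.63 ± 0.14). Lower were Gt(ROSA)26Sor (-1.48 ± 0.20), Rpgrip1 (-1.15 ± 0.16), Lgals3bp (-0.98 ± 0.16), the interferon-induced Ifitm3 (-0.67 ± 0.13) and the mitochondrial carrier Slc25a29 (-0.77 ± 0.16). Limma called 0 genes, with 319 at an unadjusted p under 0.05, 176 higher and 143 lower. Leaving out either sample of control mouse 2 removed that mouse from the means and left the female as the only control. A count of genes from that fit cannot be read as an effect of genotype. Camera called 5 lists: interferon response (median -0.84), inner hair cell and ribbon synapse (-0.29), tectorial and spiral limbus matrix (0.25), stria vascularis (0.52) and fibrocyte and mesenchyme (0.21). The adjusted p was 0.654 for each with an estimated correlation. All 5 calls were lost without control mouse 1, the female, with medians of -0.25, -0.16, -0.01, 0.09 and 0.11 in that order, and the fibrocyte call also without cKO mouse 1 (0.10). Across genes, which are not replicates, the genotype effects in apex and base correlated at r = 0.208 (Spearman's rho 0.253). When apex and base were taken from mice of different number, r was -0.143 and 0.0697, and with no mouse shared in the other 2 pairings -0.0332 and -0.162.

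Whether the genotype effect differed between apex and base was tested directly. No gene passed (0 in limma, 149 at an unadjusted p under 0.05, 73 with a higher and 76 with a lower effect in the base). The smallest p values belonged to Steap4 (1.60 ± 0.29, log2, SE), Clasrp (1.85 ± 0.34), the erythroid genes Hemgn (2.84 ± 0.61) and Gata1 (1.81 ± 0.45), and Uroc1, an enzyme of histidine breakdown (2.49 ± 0.54). On the other side stood Pcp4 (-1.24 ± 0.26), the growth factor Fgf22 (-2.82 ± 0.69), the cadherin Celsr2 (-0.92 ± 0.24), Crybb3 (-2.50 ± 0.65) and AI593442 (-1.02 ± 0.29). The sizes for Gata1, Fgf22 and Crybb3 are not exact, since 1 group mean of each lay under the filter's signal. Camera called 9 lists. The effect in the base was below that in the apex for hair bundle (median -0.22), hair cell transcription factors and soma (-0.55), outer hair cell (-0.18), inner hair cell (-0.47) and supporting cell genes (-0.24). It was above for stria vascularis (2.32), bone (0.46), cell cycle (0.29) and immediate early genes (0.55). None held with an estimated correlation (smallest adjusted p = 0.385 with an estimated correlation), and the soma and immediate early calls alone were kept when any 1 sample was left out.

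The calls on this difference that were lost without a single sample were as follows. Without control base replicate 1 the medians were 0.27 for stria vascularis, -0.32 for hair bundle, -0.34 for inner hair cell, 0.49 for bone and 0.12 for cell cycle. Without cKO apex replicate 1 they were -0.07 for hair bundle, -0.08 for outer hair cell, -0.18 for supporting cell and 0.19 for cell cycle, and without cKO apex replicate 2 0.13 for bone. Without cKO base replicate 1 they were -0.45 for outer hair cell, -0.15 for supporting cell and 0.36 for bone, and without cKO base replicate 2 -0.23 for outer hair cell and 0.21 for cell cycle. Without control apex replicate 1 outer hair cell (-0.18) and supporting cell (-0.18) were not called, without control apex replicate 2 bone (0.19) and cell cycle (0.21), and without control base replicate 2 outer hair cell (-0.21) and supporting cell (-0.27).

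The series also compares the ends of the cochlea, which differ in the sound frequency they detect. Over both genotypes, 4 basal against 4 apical samples, 157 genes passed limma's adjusted threshold, 78 higher and 79 lower in the base. Tectb, which encodes beta-tectorin of the tectorial membrane, was 63.8-fold lower in the base (-6.00 ± 0.62, log2, SE, adjusted p = 0.0164). Genes of hair cell function fell with it: Chrna9, the receptor subunit through which efferent nerves act on outer hair cells (at least 5.19-fold lower), Strc (at least 6.46-fold lower), Calb1 (-2.84 ± 0.40) and Gfi1 (-2.01 ± 0.22, adjusted p = 0.017). Others that fell were the phosphatase inhibitor gene Ppp1r17 (-3.00 ± 0.43), 4930426D05Rik (-2.27 ± 0.36), the noncoding RNA Tunar (-2.24 ± 0.21), Rassf6 (-2.23 ± 0.17), Acbd7 (-2.11 ± 0.18), Lrtm2 (-2.08 ± 0.28) and Sox2 (-1.37 ± 0.16). Higher in the base were Ppp1r1b, a regulator of protein phosphatase 1 (6.96-fold, 2.80 ± 0.26, adjusted p = 0.0141), Fam167b (at least 2.49-fold), the tendon and cartilage gene Tnmd (2.35 ± 0.35), Cytl1 (2.31 ± 0.33), the sodium-calcium exchanger Slc8a3 (2.07 ± 0.36), 1500002F19Rik (1.97 ± 0.30), the matrix gene Thbs4 (1.92 ± 0.29), Clca2 (1.84 ± 0.25), prostacyclin synthase Ptgis (1.76 ± 0.17) and the homeobox gene Nkx6-1 (1.76 ± 0.23). Pou4f3 (at least 4.31-fold lower), Myo7a (-0.76 ± 0.22), Mbp (-0.11 ± 0.08), Tubb3 (-0.11 ± 0.40) and Dicer1 (-0.14 ± 0.16) did not pass. Folds given as least values take low samples at the filter's signal, since a group mean lay under it. Lists of bone, stria vascularis and fibrocyte genes were higher in the base by camera at the preset correlation, as given below. The share of each tissue may thus differ between basal and apical samples, and it was not separated from changes within hair cells.

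The count of 157 moved widely with single samples. It was 1518 without control base replicate 1, 365 without control base replicate 2, 25 and 9 without control apex replicates 1 and 2, 5 without cKO base replicate 2, and 0 without cKO base replicate 1 or either cKO apex replicate. It was 255 with the presumed mouse as a fixed block, of which 132 were among the 157. Without the female mouse each control group held 1 sample, so a count from that fit is not given. The count was 0 with the stria vascularis score of each sample as a covariate. That score was itself higher in the base than in the apex of the cKO (1.88 and 1.63 against -1.76 and -0.56). In control mouse 2 it was 2.02 against -1.52, and in control mouse 1 -1.94 against 0.25. The covariate thus also removes part of the difference between regions, so the 0 does not trace these genes to the stria vascularis.

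Over both genotypes 5 of 16 tested genes of the hair cell transcription factor and soma list fell in the base and 11 did not pass (median -1.0), among them Smpx (-1.79 ± 0.17) and the RNA-binding Rbm24 (-1.58 ± 0.16). Of the hair bundle list 3 of 23 fell (median -0.71, Strc, the plastin Pls1 at -0.93 ± 0.14 and Fscn2, at least 2.45-fold lower), and of the outer hair cell list 2 of 6 (median -1.16, Strip2 at -1.91 ± 0.16 and the transcription factor Ikzf2 at -0.99 ± 0.15). No inner hair cell gene passed over all genes, while 5 of 10 fell adjusted over the list alone (median -0.56, Cabp2 at -1.10 ± 0.21). Of supporting cell genes 2 of 23 fell (median -0.24, Jag1 at -1.19 ± 0.13 and Sox2), and Jag1 was also the 1 Notch pathway gene of 15 that passed (median -0.15). In tectorial and spiral limbus matrix, 2 of 11 rose (Col11a2 at 1.38 ± 0.15 and Col9a2 at 1.60 ± 0.21) and 2 fell (Tectb and Otog at -1.40 ± 0.23). Its median (0.39) and camera direction were above 0, its mean (-0.30) was below, and it was not called (adjusted p = 0.0932). Bone had 2 of 10 members higher (median 0.78, Phex at 1.33 ± 0.16 and Dmp1 at 0.67 ± 0.11) and fibrocyte and mesenchyme 1 of 13 (median 0.26, Col3a1 at 0.75 ± 0.10). Stria vascularis was higher as a list (median 1.91, 10 of 11 members) with no member past the threshold, and Dct levels followed single samples as given above.

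Camera called 13 lists for base against apex over both genotypes: hair cell transcription factors and soma, hair bundle (adjusted p = 3.3e-07 for both), outer hair cell (adjusted p = 6.76e-05), inner hair cell, supporting cell, myelin and Schwann cell (median -0.27), bone (adjusted p = 3.53e-06), stria vascularis (adjusted p = 0.00048), fibrocyte, endothelium (0.33, the angiopoietin receptor Tek at 0.72 ± 0.12), immediate early (0.41), interferon response (0.68) and reported microRNA targets (0.27). None held with an estimated correlation (smallest adjusted p = 0.248 with an estimated correlation), whereas fry found the 4 hair cell lists and tonotopy candidates (median -0.09, mean -0.63) to move on balance downward, with adjusted p from 0.0126 to 0.0403. Supporting cell was not called without cKO apex replicate 1 (-0.22), cKO base replicate 1 (-0.20), control apex replicate 2 (-0.30) or control base replicate 1 (-0.26). Myelin was not called without cKO apex replicate 1 (-0.14), control apex replicate 2 (-0.16) or control base replicate 2 (-0.15). Endothelium was not called without cKO base replicate 2 (0.35) or control base replicate 2 (0.18), and immediate early not without cKO base replicate 1 (0.33) or control apex replicate 2 (0.45). Interferon response was not called without cKO apex replicate 2 (0.59), control apex replicate 2 (0.45) or control base replicate 1 (0.37). Reported microRNA targets was not called without cKO apex replicate 2 (0.25), cKO base replicate 2 (0.32) or control base replicate 2 (0.17).

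**Figure D3:**
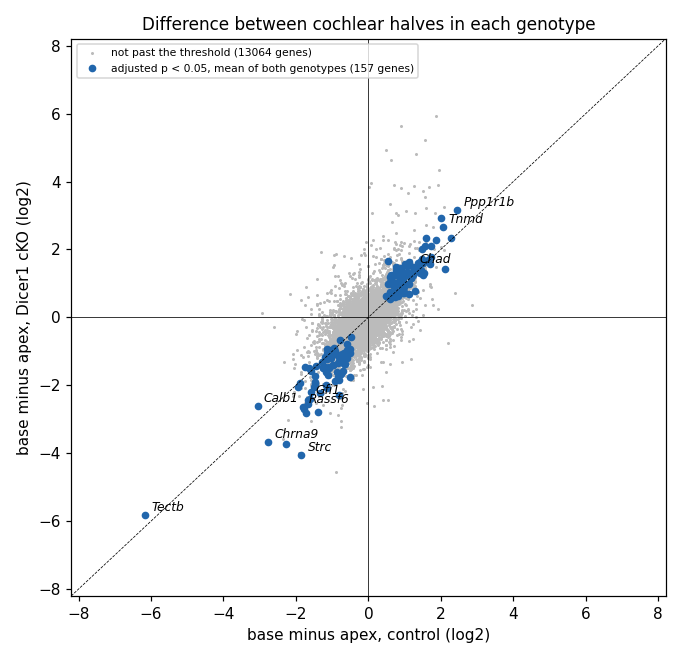
Base minus apex (log2) of each of 13221 genes in controls (x axis) and cKO (y axis), with the 157 genes past the threshold for the mean of both genotypes in blue. Over all 13221 genes, 9617 had the same direction in both genotypes, and Tectb stood lowest in both.

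Within the cKO, 2 basal against 2 apical samples, 2 of 16 genes of the hair cell transcription factor and soma list fell toward the base. These were Smpx (4.74-fold lower, -2.24 ± 0.24, log2, SE) and Rbm24 (3.97-fold lower, -1.99 ± 0.22), and the list, called by camera, had an adjusted p = 0.164 with an estimated correlation, while stria vascularis genes stood higher in the same samples (median 3.07). Also lower were Tunar (-2.70 ± 0.30), Rassf6 (-2.65 ± 0.24, adjusted p = 0.0461), Acbd7 (-2.55 ± 0.25), Slitrk6, a neurite growth regulator of the inner ear (-2.43 ± 0.25), AI593442 (-1.84 ± 0.21), Pcp4 (-1.76 ± 0.18) and Mtmr11 (-1.59 ± 0.18). Ppp1r1b (3.15 ± 0.37, adjusted p = 0.0496) and the cartilage matrix gene Chad (1.47 ± 0.16) rose. These 11 genes, 2 up and 9 down, were all that passed limma's adjusted threshold, and 1490 had an unadjusted p under 0.05. Col11a2 (1.63 ± 0.21), Smpd3 (1.58 ± 0.21) and Ptgis (1.79 ± 0.24) did not pass. Neither did Gfi1 (-2.40 ± 0.31, adjusted p = 0.0609), Sox2 (-1.48 ± 0.23), Pou4f3 (at least 6.16-fold lower, its basal mean under the filter's signal), Myo7a (-0.94 ± 0.31), Mbp (-0.20 ± 0.11), Tubb3 (-0.13 ± 0.57) and Dicer1 (-0.11 ± 0.22). The count was 0 with the presumed mouse as a fixed block. The calls were lost without any 1 of the cKO samples or either control apical sample, and more genes passed without either control basal sample. Without the female mouse each control group held 1 sample, so the spread came from the cKO alone. With the compared groups only, where the spread also came from the cKO alone, 449 genes passed. All 11 pointed the same way in controls, as did 72.7% of all genes, and control samples entered the variance that decided which genes passed.

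Camera called 11 lists in the cKO, none with an estimated correlation (smallest adjusted p = 0.164 with an estimated correlation). Hair cell transcription factors and soma (median -1.53, 2 of 16 members down over all genes and 10 adjusted over the list alone), outer hair cell (-1.47, 4 of 6 adjusted over the list alone) and hair bundle (-0.78, 9 of 23 adjusted over the list alone, Strc at least 11.6-fold lower) were lower. These 3 were also past fry's threshold (adjusted p = 0.0212, 0.046 and 0.024). Inner hair cell (-0.78), supporting cell (-0.37) and myelin (-0.21) were lower too. Bone (1.54), stria vascularis (3.07), immediate early (0.67), endothelium (0.46) and fibrocyte genes (0.24) were higher. Supporting cell was not called without cKO base replicate 1 (-0.29), myelin not without cKO apex replicate 1 (-0.14) or cKO base replicate 1 (-0.21). Fibrocyte was not called without cKO apex replicate 2 (0.17) or cKO base replicate 1 (0.10), and endothelium not without cKO base replicate 2 (0.50).

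In controls, 2 basal against 2 apical samples, Tectb was 71.4-fold lower in the base (-6.16 ± 0.88, log2, SE) and the outer hair cell gene Strip2 3.68-fold lower (-1.88 ± 0.23), but none of 13221 genes passed. Rassf6 (-1.81 ± 0.24), Flrt2 (-1.03 ± 0.15) and Acbd7 (-1.68 ± 0.25) were on the same side. Smpd3, a sphingomyelinase of cartilage and bone (1.71 ± 0.21), Chad (1.24 ± 0.16), Pcolce2 (1.28 ± 0.17), Ptgis (1.74 ± 0.24) and the protease inhibitor Serpina3n (1.51 ± 0.22) were on the other, and the adjusted p of all 10 was 0.226. Gfi1 gave -1.62 ± 0.31, Sox2 -1.25 ± 0.23, Pou4f3 -1.59 ± 0.82, Myo7a -0.59 ± 0.31, Mbp -0.03 ± 0.11, Tubb3 -0.10 ± 0.57 and Dicer1 -0.18 ± 0.22. Limma called 0 genes, with 994 at an unadjusted p under 0.05, 508 higher and 486 lower. Without control base replicate 1 or without the female mouse, a compared group held 1 sample. A count of genes from those fits cannot be read as a difference between regions. The test of the difference between genotypes called 0 genes, as given above. Across genes, which are not replicates, base minus apex in controls and cKO correlated at r = 0.637 (rho 0.612).

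Camera called 8 lists in controls, none with an estimated correlation (smallest adjusted p = 0.44 with an estimated correlation) and none by fry. Hair cell transcription factors and soma (median -0.48, 5 of 16 down adjusted over the list alone), hair bundle (-0.50), outer hair cell (-0.85, 2 of 6 down adjusted over the list alone) and myelin (-0.20) were lower in the base. Fibrocyte (0.27), bone (0.65), interferon response (0.89) and reported microRNA targets (0.23, with Sox2 the 1 member past the threshold adjusted over the list alone, downward) were higher. The soma and hair bundle calls were kept when any 1 sample was left out. Outer hair cell was not called without control apex replicate 2 (-0.60) or control base replicate 1 (-0.41). Myelin was not called without either cKO apical sample (-0.20 in both), control apex replicate 2 (-0.13) or control base replicate 2 (-0.01), and fibrocyte not without control base replicate 2 (0.18). Bone was not called without control apex replicate 1 (0.45) or control base replicate 2 (0.53), and interferon response not without control apex replicate 2 (0.58) or control base replicate 1 (0.08). The microRNA targets were not called without control apex replicates 1 (0.20) or 2 (0.23) or control base replicate 2 (0.06).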

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

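The tests of explanations in this part and the neutrophil granule and erythroid precursor lists were chosen after the results were seen; the other list tests were planned. The genotype effect differed between the base and the apex for 9 of 25 fixed gene lists in a test of the difference itself, camera at the preset correlation on the base effect minus the apex effect. The median differences (log2) were -0.22 for hair bundle and mechanotransduction, -0.55 for hair cell transcription factors and soma, -0.18 for outer hair cell, -0.47 for inner hair cell and ribbon synapse, and -0.24 for supporting cell. They were 2.32 for stria vascularis, 0.46 for bone, 0.29 for cell cycle and 0.55 for immediate early and heat shock. None of the 9 passed with an estimated correlation (smallest adjusted p = 0.385 with an estimated correlation). The median differences of the neutrophil granule (1.02) and erythroid precursor lists (1.1) are given as values only, since these lists were built from genes seen to differ in these samples, which settled any test of them beforehand. These medians ran from 0.51 to 1.27 and from 0.70 to 1.56 when single samples were left out, both lowest without control base replicate 1.

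Hair cell genes were lower in the cKO basal samples, with a soma list median of -0.43 (log2) and 10 of 16 members lower. No member passed over all genes, and the camera call was lost with an estimated correlation (adjusted p = 0.424). The median was smaller in size without cKO base replicate 1 or control base replicate 2, and with low values raised to the filter, as given above. A larger share of other tissue in the cKO basal samples may account for the lower values, since supporting cell genes were lower alongside (median -0.25). The hair cell score minus the supporting cell score differed by -0.14 between the genotypes, with cKO values of -0.53 and -0.41 touching, as rounded, the control values of -0.26 and -0.41. Scores of other tissues did not part the genotypes, however. Stria vascularis was at 1.88 and 1.63 in the cKO and at -1.94 and 2.02 in control base replicates 1 and 2. Bone was at 1.44 and 0.24 against -0.28 and 0.40, so whether other tissue was the cause stays open. Another candidate is 1 control basal sample with few stria vascularis transcripts. Without it the median was -0.48, no smaller, though the camera call was lost with 1 basal control left. The score of the soma list was -0.38 in that sample and -0.39 in the other control, against -0.93 and -0.56 in the cKO. For this list the values argue against that sample as the source of the difference, as far as 2 controls can show. A loss of hair cells or of their transcripts in the cKO, the difference the design names, remains a hypothesis. It was not separated from a larger share of other tissue.

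Interferon response genes were lower in the cKO samples of both regions, with medians of -0.63 in the apex and -1.05 in the base. No member passed over all genes. Camera with an estimated correlation called no list in either region (smallest adjusted p = 0.819 in the apex and 0.424 in the base). A candidate explanation is 1 control mouse with high levels of these genes: without the female control mouse the medians were -0.29 and -0.14, and the adjusted p was 0.101 and 0.369. In the base the log2 signal was 9.22 in that mouse, 7.39 in the male control and 7.07 and 7.06 in the cKO for Irf7, and 9.06, 8.11, 7.35 and 7.19 for Usp18. Oas1a too was higher in the male control (8.31) than in the cKO (7.97 and 8.04), while Ifit3 was at 8.55 in the male control, between the cKO values of 8.68 and 8.46. In the apex the male control stood above both cKO samples for each of these genes, those of smallest p in the list. The values were 7.11 against 6.06 and 6.33 for Irf7 and 6.82 against 6.63 and 6.46 for Usp18. For Oas1a they were 8.49 against 7.99 and 8.16, and for Ifit3 8.10 against 7.81 and 7.76. In the female the apical signal was 7.21 for Irf7 and 8.42 for Oas1a, close to the male control. It was 7.98 for Usp18 and 8.85 for Ifit3, above that mouse. With 1 male control, how much of the difference the female mouse accounts for stays open. Sex, an infection or another state of that mouse, and an effect of the genotype remain open, since no other female was measured.

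In both regions, 8 genes differed between genotypes in the same direction at an unadjusted p under 0.01, where 0.66 are expected if apex and base were independent, which samples of the same mice are not: Tmem267 and Pnmt higher, and Rtp4, Rpgrip1, Slc25a29, Lgals3bp, Gt(ROSA)26Sor and Smim10l1 lower in the cKO. Variants linked to the floxed Dicer1 allele on chromosome 12 are argued against as the whole cause, since 7 of the 8 genes lie on another chromosome, with Slc25a29 the exception. At an unadjusted p under 0.05 in both regions and the same direction, 4 of 42 genes lay on chromosome 12. It held 471 of the 13171 tested genes with a known chromosome (p = 0.0621, Fisher's exact test), and the highest count on another chromosome was 5. A sequence variant under the probes of 1 probe set stays open, because only 2 of the genes have another probe set above the filter: of the 4 of Slc25a29, 1 shifted as far, and of the 3 of Smim10l1, 0 did. The 3 of Smim10l1 were lower in the cKO too, at -0.46, -0.39 and -0.23 over both regions against -1.18 for the probe set used. Unlinked differences in strain background between the mice, and an effect of Dicer1 loss, may also account for the shifts and were not tested.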

How the results depend on the processing

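Leaving out the female control mouse, the stria vascularis score as a covariate, low values raised to the filter and the presumed mouse as a block in the list test were chosen after the data were seen; the other alternatives were planned. No alternative gave a gene past the threshold for the genotype effect in the apex or the base beyond the following. Without an intensity trend 1 gene passed in the apex and 1 in the base; with an unadjusted p under 0.01 and a 2-fold change as the criterion, 18 passed in the apex, 31 in the base, 13 over both regions and 12 for the difference between regions. Over both regions 1 gene passed with the presumed mouse as a random block and 1 with 8 samples taken as independent. Leaving out single samples gave 0 to 0 genes in the apex, 0 to 37 in the base, 0 to 9 over both regions and 0 to 0 for the difference. A sample left alone in its group was assumed to vary like the other groups. The highest counts in the base and over both regions arose where the female mouse was the only control left in the comparison.

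For base against apex in controls, 157 genes passed without the female mouse, 119 by the unadjusted criterion, and 0 to 551 without single samples. In the cKO the 11 genes became 0 with no filter, with quantile normalization, with 75th percentile centring, with every probe set on its own, without an intensity trend, with the presumed mouse fixed and with the stria vascularis covariate. They became 6 with the mean of the probe sets, 81 with the mouse random, 449 without the female mouse, 449 with the compared groups only, 51 at an adjusted p under 0.1, 302 by the unadjusted criterion, and 0 to 316 without single samples. For the mean of both genotypes the 157 became 98 with the mean of the probe sets, 70 without an intensity trend, 1049 without the female mouse, 255 with the mouse fixed, 527 with the mouse random, 0 with the stria vascularis covariate, 495 at an adjusted p under 0.1, 269 by the unadjusted criterion, and 0 to 1518 without single samples. Looser thresholds admit more genes by construction; the cause of the other shifts was not tested. In a fit of base against apex with no genotype term, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, gave as many genes (467, against 8 in the highest other split). That share is under 0.05 only with the 8 samples taken as independent, which samples of the same mice are not. Chance is therefore not excluded for that count, nor for the 157. The 8 splits that part all presumed pairs, the real one among them, also gave 467 and at most 8, and are too few for a share under 0.05.

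The correlation of genotype effects between apex and base (0.208) was 0.0447 with no filter, -0.143, 0.0697, -0.0332 and -0.162 in the 4 pairings with no mouse shared, and 0.0143 to 0.244 without single samples. Every call of a fixed list was lost with an estimated correlation (0 of 25 lists in each of the 7 contrasts). With fry 0 passed in the apex, base, mean of regions, difference and control contrasts, 3 in the cKO and 5 over both genotypes. Quantile normalization left 1 list in the apex, and without the female mouse 4 were called in the base and 2 over both regions. Without single samples the number of lists was 2 to 8 in the apex, 4 to 15 in the base, 2 to 12 over both regions, 5 to 13 for the difference, 7 to 11 in controls, 9 to 12 in the cKO and 10 to 13 for the mean. The camera direction of 9 list values reversed, to the following medians. Tectorial in the apex (0.31) stood at 0.05 without control apex replicate 1, in a range of 0.05 to 0.52 over single samples left out. Stria vascularis in the base (1.31) was at -0.18 without control base replicate 1 or the female mouse (range -0.18 to 3.32). Over both regions (0.52) it was at 0.09 without either sample of that mouse or the whole mouse (range 0.09 to 1.02), and for the difference (2.32) at -0.24 without the female mouse. Glial scar in the base (0.31) was at -0.04 without the female mouse, and myelin in controls (-0.20) at -0.01 without control base replicate 2 (range -0.55 to -0.01). The cause was not tested. Of the other list values 681 kept their direction and side of the threshold and 264 no longer passed; of the gene values 2530 were kept, 297 no longer passed, 58 newly passed and 96 moved. All scalings moved the median of all genes by 0.043 or less. Signal over background could not be judged, since no detection calls were at hand, and the filter at a signal of 38.71 stands in for it.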

Other observations

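The neutrophil granule and erythroid precursor lists were chosen after their genes were seen among those of smallest p, so a test of them on these samples was settled by the choice and carries no weight. In the cKO basal samples all 13 tested neutrophil granule genes, which serve antimicrobial defence in white cells, were higher than in controls (median 1.23, log2), among them Ngp (1.16 ± 0.28, SE) and Ltf (0.93 ± 0.22). In the apex 11 of 13 were higher (median 0.22). All 9 tested erythroid precursor genes were higher in the cKO basal samples (median 0.53, Hemgn at 1.88 ± 0.43), while 8 of 9 were lower in the apex (median -0.42). Control base replicate 1 had the lowest scores of both lists, -0.94 and -0.79 against -0.10 and -0.20 in replicate 2, and without it the basal medians were 0.81 and 0.28. The erythroid basal median was 0.90 without cKO base replicate 1 and 1.0 without control base replicate 2. In the apex the neutrophil median was 0.02 without control apex replicate 1 and 0.45 without control apex replicate 2, and the erythroid median -0.21 without cKO apex replicate 2 and -0.16 without control apex replicate 2. Of 10 bone genes, 8 were higher and 2 lower in the cKO basal samples and none passed (median 0.22, and 0.06 without control base replicate 1), with Mmp9 at 2.15 ± 0.83 and the osteoblast factor Sp7 at -0.14 ± 0.27. The call of that list was lost with an estimated correlation (adjusted p = 0.424 with an estimated correlation).

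Among sex-linked genes, Kdm5d, a Y-linked demethylase, was at a log2 signal of 8.47 in both cKO apical samples and at 8.19 and 8.32 in the cKO basal samples. In the male control mouse it was at 6.35 in the apex and 5.95 in the base, and in the female at 3.25 and 3.19. Uty, another Y-linked gene, was at 8.25 and 8.57 in the male control and between 7.76 and 8.54 in the cKO samples. The Y-linked Eif2s3y differed between mice of the same genotype. It was at 8.12 and 7.60 in the apex and base of cKO mouse 1, 10.30 and 10.17 in cKO mouse 2, and 8.97 and 8.58 in the male control. Over both regions Kdm5d was at least 6.27-fold higher in the cKO than in the mean of the control mice, the female included (adjusted p = 0.999, limma). Control samples under the filter's signal were taken at it. Without the female the difference was 2.21 ± 0.20 (log2, SE), against 1 male control.

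Calb1 gave 0.93 ± 0.57 in the apex and 1.37 ± 0.57 in the base (log2, SE), without passing over all genes or adjusted over the list alone. Its log2 signal was 9.92 and 9.88 in the cKO apical samples, 7.97 and 9.97 in the control apical samples, 7.05 and 7.51 in the cKO basal samples, and 5.80 and 6.01 in the control basal samples. Lgals3, a galectin of macrophages, gave 0.87 ± 0.32 in the apex and 1.08 ± 0.32 in the base, while the macrophage and leukocyte list had medians of 0.04 and 0.12 and was not called.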
